A study of Mus musculus with 6 samples.

How the data were processed

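RNA was measured by sequencing in gastrocnemius muscle of 6 mice, 3 given inotodiol and 3 given vehicle. The labels mark the samples of a group as biological replicates, and each sample has 1 table. The deposited values are whole-number read counts per gene symbol, with no normalization by the authors that the values show. Per the submitters' processing notes, Bowtie2 and bedtools were used with the mm10 build of the mouse genome; their versions and settings, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Per the labels' protocols, libraries were made from total RNA with a Lexogen Quant-Seq kit. Whether the counts come from transcript ends alone, or rise with transcript length, was not settled and neither was assumed; the very long Ttn transcript had 329803 to 514209 counts per library. The deposited counts of Xist and of its antisense partner Tsix were nearly equal in every library, so counts of overlapping genes on opposite strands were treated as not separable. Reads of near-identical genes (the Mup, Serpina1 and globin families, ribosomal protein genes with pseudogenes) could have been split or counted more than once, and single members of these families are uncertain.

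Each table held 23282 rows, of which 44 repeated a symbol and were kept as separate rows. Total counts ranged from 8961893 to 9953764 per library. Genes were kept with edgeR's filterByExpr at its default settings (minimum count 10, minimum total count 15), which left 11700 genes for testing and 11582 rows out, 6791 of them with 0 counts in all samples. No gene of the mitochondrial genome was in the tables analysed here. Counts were scaled with TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were computed from the fitted weights and the moderated quasi-dispersion, and 95% intervals from the total degrees of freedom. The common biological coefficient of variation was 27.2%. CPM values are TMM-scaled unless given as unscaled CPM, which are relative to the library total alone. P-values of the gene tests measure the spread among 3 animals per group.

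Before the data were examined, 43 gene lists were fixed, 31 of pathways and complexes and 12 of cell types that a muscle sample could hold. Lists with at least 5 genes kept were tested with camera from limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, with adjustment over all lists tested. Camera with an estimated correlation and fry were run beside it. The preset correlation takes list members as nearly independent, so its p-values hardly carry how members vary together between mice. The estimated correlation was 0.59 for the cytosolic ribosome list and 0.17 for the complex I list. The genes named were also set by a rule fixed beforehand. Among genes with a mean of at least 5 CPM, a descriptive symbol and groups that did not overlap, up to 12 called genes per direction were to be named; with fewer than 5 calls in a direction, the genes with the smallest p filled it to 10, as values and not as calls. A set of 14 genes of the liver X receptor, mitochondrial and atrophy pathways was named whatever the result, with up to 4 members of each list described, those with the smallest p; some of these members are not reported here. Lists of hepatocyte, exocrine pancreas, sex-biased liver and Y-linked genes were written after the data had been seen.

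The gene test was tried on counts simulated from the real means, library sizes and fitted dispersions for the comparison of inotodiol with vehicle, over 11700 genes with 50 genes changed at each size. The changed genes were drawn from those with a mean of at least 5 CPM. All sizes were changed in the same run, which makes the adjusted threshold easier to pass than where few genes change. The test recovered 6% of genes changed 1.5-fold, 40% at 2-fold, 96% at 4-fold and 98% at 8-fold, and called 7 unchanged genes. In the simulated list test, over 11393 genes, 1 list of 30 members shifted by 0.4 on the log2 scale was called, and 0 of 20 unshifted lists. The simulated genes varied independently of one another, so this run cannot show how often lists of correlated genes are called without a shift. The shift was also larger than the medians of the lists called in the real data, 0.12 for the cytosolic ribosome and 0.15 for complex I.

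The alternatives were RLE, upper-quartile and library-total scaling, no filter and a stricter filter (1 CPM in all 6 samples), DESeq2 1.42.0, limma-voom, edgeR's robust option, the replicate number as a block, a threshold of 0.10, each library left out in turn, a prior count of 0.5 and the other set tests. Runs without the hepatocyte and exocrine pancreas genes and without Rn45s were added after the data were seen. Gene coordinates are whole-gene spans from GENCODE M21, whose GRCm38 assembly is the one named mm10. Rn4.5s and Ctgf had no entry under these symbols there.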

Results

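Transcripts were counted in gastrocnemius muscle of 20-month-old wild-type C57/BL6J mice that had received inotodiol, a lanostane triterpenoid of the chaga mushroom, or vehicle by mouth every day for 10 weeks. The dose was 0.35 mg/kg and each group had 3 mice. The series title places the study in age-related muscle wasting, mitochondrial function and the liver X receptor beta, so the comparison asks which muscle transcripts differ between treated and untreated old mice. Libraries held from 8961893 to 9953764 counts, and 11700 genes passed the filter on low counts. The precursor ribosomal RNA Rn45s took 3.97%, 6.82% and 4.38% of the counts in vehicle libraries 1 to 3 and 10.2%, 9.56% and 4.33% in inotodiol libraries 1 to 3. Pearson correlations of log2 CPM between libraries ranged from 0.943 to 0.950 over the 6 pairs within groups and from 0.937 to 0.955 over the 9 pairs between groups, so libraries of different groups were about as similar as libraries of 1 group. The first principal component held 23.7% of the variance and did not part the groups. Of the 30 genes with the highest loadings on its positive side, 24 belonged to the hepatocyte list or to the Mup and Serpina1 families.

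No gene differed between inotodiol and vehicle at an adjusted p under 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.58. At an unadjusted p under 0.05 there were 570 genes, 312 higher and 258 lower with inotodiol, against 585 that chance gives among 11700 tests. DESeq2 called 1 gene, Gc, the vitamin D binding protein made by the liver, at a log2 fold change of 3.03 and an adjusted p of 0.0037. The groups did not overlap for 1218 genes (602 higher, 616 lower), which is 10.4% of those tested, where chance gives 10% for 3 against 3. The median standard error of a log2 fold change was 0.28. In counts simulated with the real library sizes and fitted dispersions, the changed genes were drawn at random among those with a mean of at least 5 CPM. Of these, 96% of genes changed 4-fold were recovered and 40% of those changed 2-fold. Recovery of genes under 5 CPM was not tried, and genes that vary more between mice are harder to detect. None of the 19 hepatocyte genes tested, all with a log2 fold change of at least 2.07, was called. With library totals in place of TMM scaling the median log2 fold change of all genes moved from -0.00073 to -0.12, and 138 of 726 genes at an unadjusted p under 0.05 were then higher, against 312 of 570. Without inotodiol replicate 3 the count of called genes was 25, and without a filter on low counts it was 95. Of these, 20 of the 25 and 38 of the 95 belonged to the hepatocyte list or to the Mup and Serpina1 families.

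The genes with the smallest p among those higher with inotodiol were mostly genes of the liver. Of the 10 named by the rule, 6 were in the hepatocyte list and 7 with the Mup and Serpina1 families added. Alb, serum albumin (chromosome 5, 90460897 to 90476602), had 17.6 ± 11.5 CPM in vehicle and 132 ± 109 CPM in inotodiol muscle (SD, n = 3), a log2 fold change of 2.91 ± 0.54 (SE). Serpina3k had a log2 fold change of 2.90 ± 0.60, Cyp3a11, a liver cytochrome P450, of 3.18 ± 0.71, Ttr, the thyroid hormone carrier transthyretin, of 2.82 ± 0.62, and Fabp1, the liver fatty acid binding protein, of 3.07 ± 0.74. Gc stood at 3.03 ± 0.60 and Serpina1e at 2.61 ± 0.59 on the same scale. All of these had an adjusted p of 0.58 in edgeR; all passed the threshold with no filter on low counts, and all but Fabp1 without inotodiol replicate 3. Without inotodiol replicate 1 the log2 fold changes of Alb, Ttr and Fabp1 were 2.03, 1.72 and 1.97, and without vehicle replicate 2 they were 3.50, 3.27 and 4.33. The 26 hepatocyte genes together took 18.0, 104 and 67.2 unscaled CPM in vehicle libraries 1 to 3 and 763, 313 and 120 in inotodiol libraries 1 to 3, with exact 95% binomial intervals of 113 to 127 for inotodiol 3 and 97.7 to 111 for vehicle 2 that cover counting error only. The group means were 63.1 ± 43.3 and 399 ± 330 unscaled CPM (SD, n = 3). The share of Rn45s was likewise highest in inotodiol 1 and 2 and lowest in vehicle 1. Unlike the hepatocyte genes, it was lower in inotodiol 3 (4.33%) than in vehicle 2 (6.82%) and vehicle 3 (4.38%). Rn45s itself was called higher by edgeR without inotodiol replicate 3 (log2 fold change 1.12, adjusted p 0.032). It was also called with no filter on low counts (0.80, adjusted p 5.3e-04). The 16 exocrine pancreas genes took 128 unscaled CPM in inotodiol 1 and at most 3.14 unscaled CPM in the other libraries. Both lists were written after the data had been seen.

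**Figure D1:**
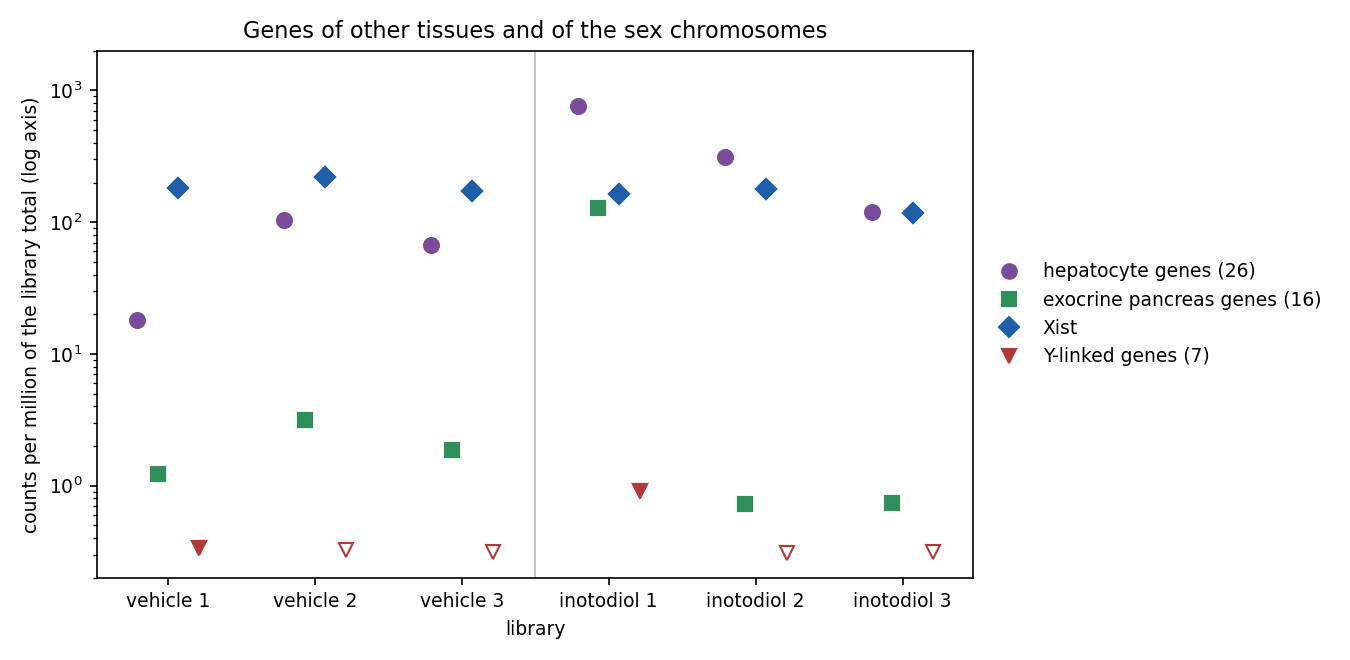
Unscaled CPM, relative to the library total (log axis), in each of the 6 libraries for the summed hepatocyte genes (circles), summed exocrine pancreas genes (squares), Xist (diamonds) and summed Y-linked genes (triangles), with values under 3 counts drawn open at the level of 3 counts. Hepatocyte genes reached 763 in inotodiol 1, pancreas genes 128 in that library, and Xist lay between 117 and 218 in all 6.

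Among the named genes that are not in the liver groups, Golga3, a golgin of the Golgi apparatus (chromosome 5, 110176701 to 110226470), had 17.4 ± 1.91 CPM in vehicle and 32.1 ± 1.49 CPM in inotodiol muscle, a log2 fold change of 0.89 ± 0.19 (95% interval 0.49 to 1.29). Rn4.5s had a log2 fold change of 1.34 ± 0.31 and Wfdc21 of 2.08 ± 0.49. Wfdc21 had 19, 19 and 33 counts in vehicle libraries 1 to 3 and 171, 72 and 44 in inotodiol libraries 1 to 3, an order the hepatocyte genes share in the inotodiol libraries, and its log2 fold change was 1.35 without inotodiol replicate 1. On the lower side none of the 10 named genes was in the hepatocyte list, and whether they share a function was not tested. Fam214a (chromosome 9, 74952884 to 75032468) had 22.6 ± 1.52 CPM in vehicle and 11.4 ± 1.48 CPM with inotodiol, a log2 fold change of -0.99 ± 0.21. Pdk4, the kinase that inhibits pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), had 169 ± 49.95 and 86.7 ± 22.4 CPM, a log2 fold change of -0.96 ± 0.21. The inward rectifier channel gene Kcnj2 stood at -1.08 ± 0.26, the glycine transporter gene Slc6a9 at -1.10 ± 0.28, Nfkb2, a subunit of NF-kB, at -0.78 ± 0.20 and Cyp26b1, which degrades retinoic acid, at -0.86 ± 0.22. Ctgf had a log2 fold change of -0.92 ± 0.25, Hgs of -0.81 ± 0.21, Smim14 of -0.70 ± 0.17 and S1pr1 of -0.67 ± 0.18. In each of these genes all 3 inotodiol values lay on 1 side of all 3 vehicle values, which the rule required, and none passed the adjusted threshold, with adjusted p from 0.58 to 0.64 in edgeR. With no filter on low counts Golga3, Rn4.5s, Wfdc21, Fam214a, Pdk4, Kcnj2, Nfkb2, Cyp26b1 and Ctgf passed it, and Wfdc21 also without inotodiol replicate 3.

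**Figure D2:**
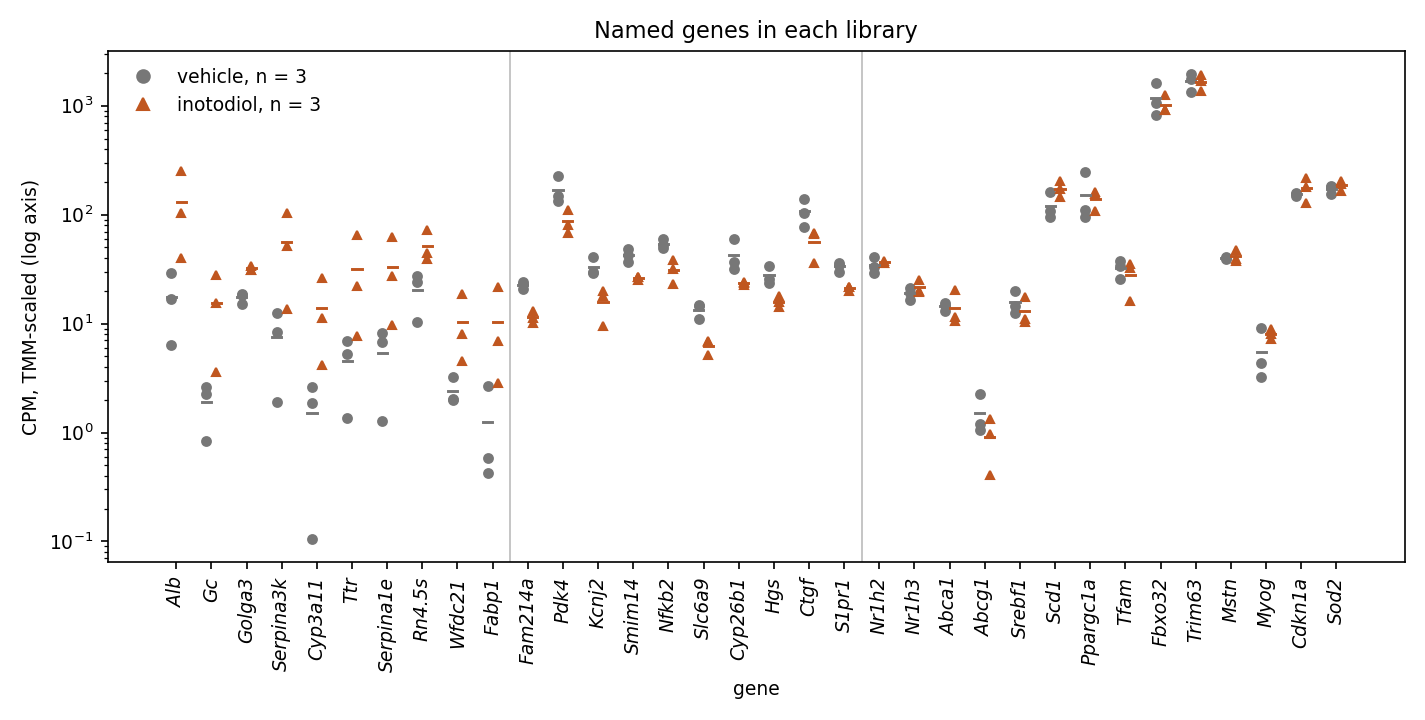
TMM-scaled CPM (log axis) of the named genes in each of the 3 vehicle libraries (grey circles) and 3 inotodiol libraries (orange triangles), with lines at the group means; the first block holds the genes named as higher, the next those named as lower, and the last the genes fixed beforehand. The inotodiol values of Alb lay between 39.8 and 252 CPM and its vehicle values between 6.42 and 29.4 CPM.

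Among the lists of mitochondrial respiration, 1 of 4 was called, and not with an estimated correlation. Of the 36 nuclear genes of complex I, the NADH dehydrogenase of the respiratory chain, 30 had a log2 fold change above 0, with a median of 0.15, and camera called the list higher (adjusted p 0.0064), but adjusted p = 0.92 with an estimated correlation. Ndufv1 had a log2 fold change of 0.35 ± 0.13, Ndufa5 of 0.31 ± 0.12, Ndufb4 of 0.32 ± 0.14 and Ndufa11 of 0.30 ± 0.14. The medians were 0.15 for complexes II and III, 0.17 for complex IV and 0.14 for ATP synthase, with adjusted p of 0.14, 0.099 and 0.12, none of them called; with limma-voom all 3 were called higher (adjusted p 0.012, 0.0038 and 0.0070). Cycs, which encodes cytochrome c, had a log2 fold change of 0.28 ± 0.13, Cox5b of 0.27 ± 0.12 and Atp5g1 of 0.26 ± 0.12. Over the 81 genes of these lists together 65 were above 0 and the median fold was 1.11, with camera p = 9.3e-06 at the preset correlation and p = 0.19 with an estimated one. No member passed the gene test over all genes or adjusted over the list alone. The cytosolic ribosome list was the other list called higher (adjusted p 0.0023), with 68 of its 79 members above 0 and a median of 0.12, and adjusted p = 0.92 with an estimated correlation. Rps27 had a log2 fold change of 0.63 ± 0.21, Rps13 of 0.40 ± 0.16 and Rpl26 of 0.31 ± 0.13. Both calls ended without inotodiol replicate 3, where the ribosome median was 0.038 (adjusted p 0.48) and the complex I median 0.10 (adjusted p 0.34), and both ended with library-total scaling, where the medians were 0.0068 and 0.036. The ribosome call also ended without vehicle replicate 2 (median 0.10, adjusted p 0.13), and the complex I call without vehicle replicate 3 (median 0.15, adjusted p 0.074). Without inotodiol replicate 2 the ribosome call was stronger (camera adjusted p 5.0e-07). Over all alternatives the ribosome median ranged from 0.0068 to 0.21 and the complex I median from 0.036 to 0.19. With inotodiol replicate 3 included, the mean level of the complex I genes in that library was 0.14 above their mean over all libraries on the log2 scale, against 0.028 and 0.017 in inotodiol 1 and 2 and -0.075, -0.043 and -0.068 in vehicle 1 to 3, so the groups did not overlap. The groups did not overlap for complexes II and III or ATP synthase either, and overlapped for complex IV. Chance gives no overlap in 10% of cases for 3 against 3. The fast fibre and muscle stem cell lists, which were not called, did not overlap either. Complexes II and III were parted by mean levels of -0.020 in inotodiol 1 and -0.024 in vehicle 2 alone, so these separations are weak support. For the ribosome list these levels were 0.055, -0.098 and 0.23 in inotodiol 1 to 3 and -0.077, -0.14 and 0.031 in vehicle 1 to 3, so the groups overlapped.

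**Figure D3:**
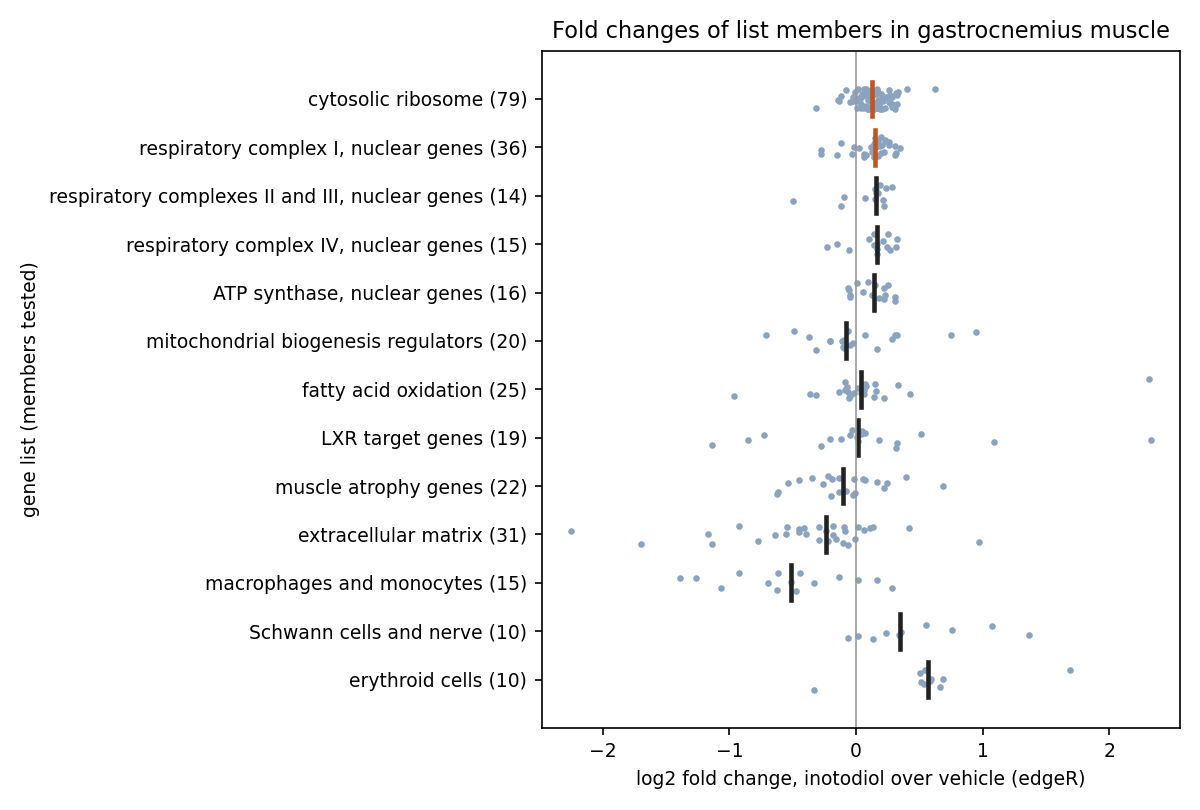
Log2 fold changes (inotodiol over vehicle) of the tested members of 13 gene lists, 1 point per gene with vertical scatter added, with a bar at each list's median; orange bars mark the lists called by camera with the preset correlation. The medians of complex I and the cytosolic ribosome were 0.15 and 0.12, while single extracellular matrix genes reached -2.25.

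Regulators of mitochondrial biogenesis were not called as a group. The median of the 20 genes was -0.078 (adjusted p 0.91), and the mean of the same members was 0.00020, of the other sign. Ppargc1a, the coactivator that drives mitochondrial biogenesis, had 150 ± 82.9 CPM in vehicle and 141 ± 29.0 CPM with inotodiol, a log2 fold change of -0.094 ± 0.29. Tfam, which maintains mitochondrial DNA, stood at -0.21 ± 0.26, Tfb2m at -0.49 ± 0.21 and Sirt3 at 0.75 ± 0.41. In the fatty acid oxidation list (25 genes, median 0.037, adjusted p 0.76) Pdk4 was the 1 gene called when p was adjusted over the list alone, and no gene was called over all genes tested.

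Targets of the liver X receptors were not called as a group. Among the 19 genes tested 11 were above 0 and the median log2 fold change was 0.016 (camera adjusted p 0.85). No difference was detected in the receptor genes themselves. Nr1h2, which encodes liver X receptor beta (chromosome 7, 44549616 to 44553951), had 34.4 ± 6.28 CPM in vehicle and 36.4 ± 1.06 CPM with inotodiol, a log2 fold change of 0.081 ± 0.18 (95% interval -0.31 to 0.47). Nr1h3, the alpha receptor, stood at 0.18 ± 0.21, and from 0.067 to 0.27 with single libraries left out. The cholesterol exporter Abca1 had a log2 fold change of -0.050 ± 0.28 (95% interval -0.64 to 0.55), Abcg1 of -0.73 ± 0.78 and Srebf1 of -0.27 ± 0.28; with single libraries left out Abcg1 ranged from -1.11 to -0.31 and Srebf1 from -0.55 to -0.067. Adjusted over the list alone, 2 genes were called higher, against 0 over all genes. These were Fasn, fatty acid synthase, at 1.09 ± 0.32 and Apoc1, an apolipoprotein of liver and macrophages, at 2.33 ± 0.66; with no filter on low counts both passed over all genes. Apoc1 had 2.26 ± 0.95 CPM in vehicle and 11.4 ± 12.3 CPM in inotodiol muscle (SD, n = 3), and the 19 hepatocyte genes tested all lay higher beside it, at log2 fold changes from 2.07 to 3.31, with none called after the filter. Scd1, which desaturates fatty acids, stood at 0.51 ± 0.19. Fasn had a standard deviation of 21.7 CPM around a mean of 45.7 CPM in the inotodiol group. The cholesterol synthesis and uptake list had a median of -0.040 and a mean of 0.029 (adjusted p 0.67), with Sc5d at 0.63 ± 0.24 and Hmgcs1 at 0.55 ± 0.22.

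No gene of the muscle wasting list passed edgeR's test over all genes with the filter and all 6 libraries. The atrophy list had 15 of its 22 members below 0, a median of -0.11 and an adjusted p of 0.51. The ubiquitin ligase genes Fbxo32 and Trim63 had log2 fold changes of -0.20 ± 0.21 and -0.022 ± 0.16, at 1176 ± 411 and 1693 ± 314 CPM in vehicle muscle. Adjusted over the list alone, Nedd4, another ubiquitin ligase, was called lower at -0.61 ± 0.17 and Txnip, an inhibitor of thioredoxin, at -0.54 ± 0.15, whereas neither passed over all genes (adjusted p 0.66 for both). Over all genes both passed with no filter on low counts, and Txnip without inotodiol replicate 3. Mstn, which encodes the growth inhibitor myostatin, stood at 0.054 ± 0.16, the myogenic factor Myog at 0.54 ± 0.39 (0.27 to 1.10 with single libraries left out), the cell cycle inhibitor Cdkn1a at 0.18 ± 0.17 and the mitochondrial dismutase gene Sod2 at 0.12 ± 0.14. Over all alternatives Sod2 ranged from 0.0084 to 0.21. The fast fibre list had 16 of 17 members above 0 with a median of 0.078 (adjusted p 0.14, called only with limma-voom), led by Tpm1 at 0.28 ± 0.10, and the slow fibre list had a median of 0.0087 (adjusted p 0.67). The muscle stem cell and regeneration list had a median of 0.23 (adjusted p 0.33), with the embryonic myosin gene Myh3 at 0.58 ± 0.26. The small heat shock protein gene Hspb7 was called over its list alone at 0.71 ± 0.18 and over all genes only with no filter on low counts (adjusted p 0.60 with the filter).

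Markers of other cells in the muscle varied between single mice. Extracellular matrix genes had 25 of 31 members below 0 and a median of -0.23 (adjusted p 0.096), with Col1a1 at -1.70 ± 0.56 and Col3a1 at -1.17 ± 0.45, which passed the gene test only with no filter, as did Mbp below. Col1a1 had 98.7 ± 113 CPM in vehicle and 30.5 ± 7.68 CPM with inotodiol, and the mean level of the list in vehicle 3 was 0.71 above the mean over all libraries. Macrophage genes had 12 of 15 members below 0 and a median of -0.51 (adjusted p 0.14), where vehicle 3 lay 1.30 and inotodiol 1 lay 0.69 above the mean. Schwann cell genes had a median of 0.35 (adjusted p 0.055), with the myelin gene Mbp at 1.07 ± 0.33 and inotodiol 3 at 0.70 above the mean. Erythroid genes had a median of 0.56 (adjusted p 0.070), with inotodiol 2 at 1.04 above the mean. In the NF-kB list Nfkb2 was called over the list alone (adjusted p 0.021) and the list was not (median -0.22, adjusted p 0.20). Of the 38 lists tested, 2 were called, 4 had an adjusted p between 0.05 and 0.10, and 32 had adjusted p from 0.12 to 0.91. None was called with an estimated correlation (smallest adjusted p 0.92) or by fry (smallest adjusted p 0.27). The Schwann list was called with upper-quartile and library-total scaling, the replicate block, limma-voom and in 4 of the 6 runs with a library left out. The macrophage and matrix lists were called without vehicle replicate 1, without inotodiol replicate 1 and with limma-voom, and the macrophage list also without vehicle replicate 2. The NF-kB list was called without inotodiol replicate 1 and with limma-voom. The mitochondrial ribosome list had 49 of 75 members above 0 and a median of 0.084 (camera adjusted p 0.18), and was called higher without inotodiol replicate 1. The erythroid list was called with library-total scaling, the block, limma-voom and without vehicle replicate 1, inotodiol replicate 1 or inotodiol replicate 3. The fibro-adipogenic progenitor and tendon lists were called without vehicle replicate 1. The other 5 lists, of the mitochondrial genome, T and NK cells, B and plasma cells, neutrophils and skin, had fewer than 5 genes kept. With no filter on low counts the B and plasma cell list was tested and called lower. Of its 6 members among the genes counted, only 1 had passed the filter, Jchain at a log2 fold change of -2.08.

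The labels describe the mice as male. Xist, the RNA that coats the inactive X chromosome in female cells, had 1112 to 2018 counts per library, or 117 to 218 unscaled CPM, in all 6 libraries. The 7 Y-linked genes Ddx3y, Kdm5d, Eif2s3y, Uty, Usp9y, Zfy1 and Zfy2 together had 0 to 9 counts per library. Xist levels were 191 ± 24.1 unscaled CPM in vehicle and 154 ± 33.1 in inotodiol libraries (SD, n = 3).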

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

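Runs without the hepatocyte and exocrine pancreas genes and without Rn45s were chosen after the data were seen. They called 0 genes and 2 lists, as before. A count of 0 could not fall, and the 2 lists hold none of the genes taken out, so these runs decide little. In the first, 11681 genes were tested and Serpina1e stayed in at a log2 fold change of 2.61. The count of 0 genes at an adjusted p under 0.05 became 95 with no filter on low counts (80 higher, 15 lower) and 1 in DESeq2. It was 0 to 25 with single libraries left out, 25 without inotodiol replicate 3. Of the 25 genes, 20 were of the hepatocyte list or the Mup and Serpina1 families, and of the 95 genes, 38 were. Plg, Bhmt, Slco1b2 and Amy2a3 were among the rest of the 95, so 38 is not a full count of genes of liver or pancreas. With no filter the prior degrees of freedom rose from 9.57 to 79.9 and the quasi-dispersion of Alb fell from 6.52 to 1.62 at nearly the same log2 fold change (2.91), so for Alb the moderated spread differed and not the effect. Of the 95 genes 83 had also been tested with the filter and 12 had not, among them 4 of the exocrine pancreas list; the share of each cause in the gain was not tested. The count of 570 at an unadjusted p became 904 with no filter, where 16491 genes were tested, and ranged from 522 to 700 with single libraries left out. With the replicate number as a block 0 genes and 4 lists were called and 605 genes had an unadjusted p under 0.05. Correlations of same-numbered libraries' deviations were -0.081, 0.11 and 0.022 for numbers 1 to 3. The highest with a library of another number were 0.097, 0.018 and 0.064, so number 2 alone matched its own best. These values show no strong pairing, but with 3 libraries per group they cannot exclude one.

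The count of 2 lists became 12 with limma-voom values (the ribosome, the 4 lists of nuclear respiratory chain genes, fast fibre, glycolysis, extracellular matrix, NF-kB, macrophage, Schwann and erythroid lists), 6 at a threshold of 0.10, 0 with an estimated correlation and 0 with fry, and 1 to 9 with single libraries left out; causes were not tested. Library-total scaling also called 2, but these were Schwann and erythroid lists. Among named genes and lists that were not called, the log2 fold change or list median changed sign in these cases, where the cause was not tested. With library totals, Nr1h2 was -0.041, Mstn -0.067 and the LXR list -0.095. With the block Ppargc1a was 0.013, and with limma-voom it was 0.019 and the LXR list -0.0068. With single libraries left out, Nr1h2 ranged from -0.021 to 0.23, Abca1 from -0.40 to 0.12, Ppargc1a from -0.34 to 0.46, Tfam from -0.41 to 0.071, Fbxo32 from -0.40 to 0.11, Trim63 from -0.16 to 0.10, Mstn from -0.051 to 0.11, Cdkn1a from -0.0048 to 0.36, the LXR list from -0.024 to 0.088 and the atrophy list from -0.22 to 0.029. Without a change of sign, Myog ranged from 0.27 to 1.10, Srebf1 from -0.55 to -0.067, Abcg1 from -1.11 to -0.31, Scd1 from 0.37 to 0.76, Cyp26b1 from -1.03 to -0.54, Gc from 2.31 to 3.50, Serpina3k from 2.11 to 3.45, Cyp3a11 from 2.34 to 3.78 and Serpina1e from 1.78 to 3.04 in these runs. Over all alternatives, the 34 named genes kept their direction and side of the threshold in 527 comparisons, passed it in 24 and changed sign in 17; the 7 lists followed did so in 108, passed it in 3, lost a call in 10 and changed sign in 5.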

Other observations

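Some single genes stood apart and were picked after their values were seen. Lancl3 had 14, 13 and 13 counts in the vehicle libraries and 1, 0 and 0 in the inotodiol libraries. C530008M17Rik had 0, 1 and 1 counts in vehicle and 35, 23 and 23 in inotodiol libraries. Fam214a had 219, 221 and 213 counts against 103, 117 and 98, and Golga3 144, 172 and 187 against 288, 305 and 305, so these 4 genes varied little within groups. None was called by edgeR with the filter on low counts, where 0 genes passed and 570 had an unadjusted p under 0.05, and DESeq2 called 1 other gene, Gc; with no filter edgeR called C530008M17Rik, Golga3 and Fam214a. The interferon-induced GTPase gene Igtp had 11.5 ± 2.54 CPM in vehicle and 44.1 ± 55.8 CPM in inotodiol muscle (SD, n = 3), and the mean of the interferon list in inotodiol 1 was 0.86 above the mean over libraries on the log2 scale, against -0.55 and -0.50 in inotodiol 2 and 3. The vehicle libraries 1 to 3 stood at 0.17, -0.32 and 0.33 on this scale. The list itself had a median log2 fold change of -0.11 and was not called (adjusted p 0.51). Without inotodiol replicate 1 it was called lower, the direction opposite to that of Igtp. Igtp passed the gene test as higher with no filter on low counts (edgeR adjusted p 0.000052).

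The tests on liver, pancreas and sex-linked genes below were all chosen after the results had been seen; those on list trends and on other splits of the libraries were set beforehand.

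The summed hepatocyte genes were higher in every inotodiol library than in any vehicle library. Across the 26 genes, which are not independent replicates, pooled inotodiol and pooled vehicle counts had a Spearman correlation of 0.97, and the 16 exocrine pancreas genes reached 128 unscaled CPM in inotodiol 1 alone, so RNA carried in from abdominal organs is a candidate source. A rise of these genes in muscle under inotodiol is left open, since a tissue that expressed them at a low level could also keep their ratio. The exact two-sided permutation p of 0.10 decides nothing here, as it is the smallest that 3 against 3 allows and a group difference is expected under both explanations. Genes usually higher in male liver took 99.6% of the counts of the sex-biased liver genes over the 6 libraries, and 98.4% (248 counts against 4) without Mup20, which can share reads with other Mup genes. If these transcripts were carried in, they would be of male type in libraries that carry Xist; whether they came from other animals than the muscle was not tested, and sex bias in liver can shift with hormones.

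Xist was present in all 6 libraries labelled male. Loss of Y-linked reads in mapping or counting would leave Xist near 0 in male muscle, and the lowest level was 117 unscaled CPM, which argues against it. Y-linked counts were at most 0.55% of Xist counts in any library, which is consistent with RNA of female animals; whether the label or the animals differ was not testable here. All 6 libraries share the pattern, so it does not separate the groups.

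The ribosome and complex I lists were called with the preset correlation only. After a fit on transcript length and expression level over all genes, the median of the ribosome list went from 0.12 to 0.063 (bootstrap SE over genes 0.016). That of complex I went from 0.15 to 0.069 (SE 0.018). The fit thus took away part of each shift. The SE covers genes, not mice, and takes genes as independent, while the estimated correlation was 0.59 in the ribosome list and 0.17 in complex I. Whether such a trend accounts for the whole shift therefore cannot be told from it. In all 10 splits of the 6 libraries into 3 and 3, the real one included, at least as many lists were called, with 2 in the real split and up to 8 in the others; with an estimated correlation 0 lists were called in every split. The 10 splits are too few for a share under 0.05. For single genes the real split gave 0 calls, which all 10 splits reach by construction, so that count decides nothing; the highest other split gave 8. At an unadjusted p under 0.05, 3 of 10 splits reached the real 570 genes, with 865 the highest. The split with 865 set vehicle 1, vehicle 3 and inotodiol 3 against the other libraries. Rn45s took 3.97%, 4.38% and 4.33% of the counts in these, against 6.82% in vehicle 2, 10.2% in inotodiol 1 and 9.56% in inotodiol 2. Malat1 parted the libraries in the same way, at 5174, 5357 and 4366 CPM against 8684, 8675 and 9273 CPM in the same order. So did Ttn, at 39394, 36440 and 34573 against 52008, 48542 and 52992 unscaled CPM. The largest split thus followed a difference between libraries that is uneven between the groups and not of Rn45s alone, and its cause was not tested.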
